A study of Mus musculus with 18 samples.

How the data were processed

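RNA was measured in cells labelled as HL-1, an immortalised mouse atrial cardiomyocyte line, in 18 libraries that fall into 6 groups of 3 by the labels. The groups were cells given vehicle, cells in high glucose, and 4 groups transfected in high glucose with an inhibitor of miR-200a-3p, the negative control of the inhibitor, a mimic of miR-200a-3p or the negative control of the mimic. Transfected cells were harvested 48 h after transfection, per the labels' protocols. The glucose concentrations, the time in high glucose and whether the untransfected cells received the transfection reagent were not given in the sources used here. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

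Per the labels' protocols, stranded mRNA libraries were made from total RNA and sequenced as 150 nt paired reads on an Illumina sequencer. Reads with more than 2 N bases were discarded, adaptors and low-quality bases were trimmed with FASTX-Toolkit 0.0.13, and reads under 16 nt were dropped. HISAT2 aligned the rest to GRCm39 with 4 mismatches allowed, and uniquely mapped reads were counted, per the labels' protocols. The authors deposited a table of raw read counts per gene and a table of FPKM values (fragments scaled to transcript length and to the mapped fragments of the library). The submitters' processing notes also name DESeq2 without its role. The counting program, the annotation release and the strand setting were not given in the sources used here. Reads of overlapping antisense genes may therefore be shared, and reads that map to more than 1 place were dropped, which lowers genes with near-identical copies.

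The count table listed 29112 genes, each with at least 1 read, and held no line without a gene. The FPKM table listed 28907 of them. The 205 genes found only in the count table had at most 22 reads over all libraries. Library totals ran from 33655916 to 37928790 reads. A count of 0 allowed a level of up to 3 reads, which is 0.0791 to 0.0891 CPM (counts scaled to library size) by library, and this floor covers counting error only. The number of reads per library was similar, so depth set the same limit in every group. Between replicates, a chi-square test over genes with a mean of at least 10 reads gave 4.37 to 26.1 per degree of freedom, above the value near 1 that sequencing a library again would give. Whether libraries of a group were prepared from 1 culture was not tested. Symbols shared by 156 genes were kept apart by gene identifier.

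Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by group (minimum count 10, minimum total 15), which left 15074 genes. Library sizes were scaled by TMM. A quasi-likelihood model with 1 term per group was fitted to all 18 libraries, which gave 12 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test over the 15074 genes, unless another tool is named, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard error (SE). Levels are CPM scaled by TMM, as the mean ± SD of 3 libraries. The comparisons were high glucose with vehicle, each reagent with its own negative control, each negative control with high glucose, the negative controls with each other, and the effect of the mimic minus that of the inhibitor.

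The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names up to 12 genes higher and 12 lower in the comparisons of high glucose, mimic and inhibitor, and 5 and 5 in the others. These had the largest change among called genes with at least 5 CPM in the higher group, all 3 libraries of one group above all 3 of the other, and a symbol that is not a predicted gene model. Where no gene was called, the 4 genes with the smallest p are named. Zeb1, Zeb2, Keap1, Ctnnb1, Nppa, Nppb, Myh6, Myh7 and Txnip are named whatever their values. From each gene list described, up to 4 called members with the largest change are named, or 2 with the smallest p. Up to 6 genes lower under the mimic that carry an 8mer site for miR-200a-3p are named too. Some genes that met the rules are not reported here.

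Gene lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 33 lists with enough measured members. A further list with 4 measured members was not tested. Each list was tested again with camera and an estimated correlation, and with fry. Members past the threshold were counted over all genes and after adjustment over the list alone. No list was chosen by the study on these samples.

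Sites for miR-200a-3p were searched in annotated 3′ untranslated regions (UTRs) of the GENCODE M39 annotation and its GRCm39 sequence. Of the listed genes, 28849 (99.1%) matched this annotation, all of them on the same chromosome. Of 13059 protein-coding genes tested, 12882 (98.6%) had a canonical 3′ UTR. A site was an 8mer, 7mer-m8 or 7mer-A1 match. The median log2 fold change of genes with a site, minus that of genes with none, was compared with the same value for 419 shuffled words of the same bases. All 14444 words of 7 bases present in at least 200 genes were also ranked, with UTR length, GC content and expression as covariates. Coordinates are 1-based on GRCm39.

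The test was checked on simulated counts with the means and library sizes of the real groups, in which 50 genes were changed by each fold. Before the change, both compared groups had the means of the reference group (vehicle or negative control). Changed genes were drawn from those of at least 1 CPM in the reference group, so recovery at lower levels was not tested. Over the 14954 genes run for high glucose and vehicle, 58% of genes changed 1.25-fold were recovered and 94% of those changed 2-fold. Over 14939 genes for the mimic comparison the values were 52% and 100%, and over 14944 genes for the inhibitor comparison 68% and 96%. Among unchanged genes, 10, 7 and 10 were called.

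Alternatives set at the start were other scalings (DESeq2 size factors and upper quartile), no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fit to the compared groups alone, the replicate number as a block, a 2-fold minimum, and each library left out in turn. Chosen after seeing the data were a fit without mimic replicate 2, a correction for GC content and gene length, other scalings for the gene lists, the longest annotated UTR, and the site searches outside the mimic and inhibitor comparisons. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the site search and the plots.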

Results

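Gene expression was measured in 18 libraries labelled as HL-1 mouse cardiomyocytes, with 3 libraries in each of 6 groups, to follow the transcript changes that a miR-200a-3p mimic or inhibitor brings in a cell model of diabetic cardiomyopathy. miR-200a-3p is a microRNA of the miR-200 family, known for repression of the transcription factors Zeb1 and Zeb2. Mimics are synthetic duplexes that add microRNA activity, inhibitors block it, and each had its own negative control. Library totals were 33655916 to 37928790 reads. By log2 expression the libraries formed 3 clusters, namely vehicle with high glucose, inhibitor with its control, and mimic with its control. The first principal component held 62.8% of the variance and the second 26.2%. Across genes, the correlation of log2 CPM between libraries of a group was 0.995 to 0.996 outside the mimic group. In the mimic group replicates 1 and 3 correlated at 0.996 and replicate 2 with them at 0.981. Between the untransfected and the transfected libraries it was 0.893 to 0.920.

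**Figure D1:**
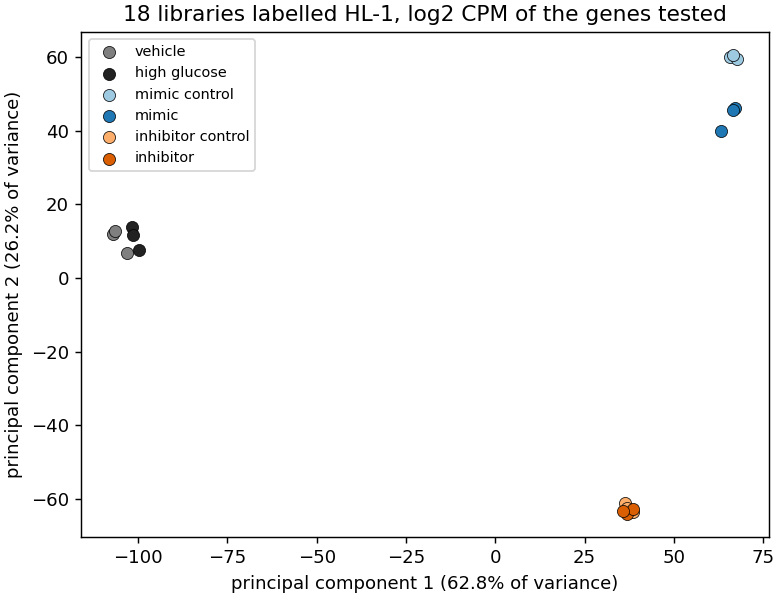
Principal components 1 (62.8% of the variance) and 2 (26.2%) of log2 CPM, 1 point per library, 3 libraries per group. The untransfected libraries, the inhibitor pair and the mimic pair lie in 3 separate clusters.

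Markers of the cell line and signs of RNA composition were measured in every group. Nppa, the atrial natriuretic peptide gene, had 1 read in the high glucose group, 1 in the inhibitor group and 0 in the other 4 groups. Myh6, the adult cardiac myosin heavy chain, lay at 0.0547 to 0.137 unscaled CPM in the group means and did not pass the filter. Tnnt2, cardiac troponin T, lay at 14.8 to 74.2 unscaled CPM and the cardiac transcription factor Gata4 at 8.75 to 11.9 unscaled CPM. These markers leave the identity of the cells, which is taken from the labels, in doubt. Reads of Rn18s, the 18S ribosomal RNA gene, made up 0.0841% to 0.181% of the inhibitor pair and 0.874% to 1.27% of the other libraries. Ribosomal protein genes took 2.84% to 3.19% of the reads in the untransfected libraries, 3.76% to 3.94% in the inhibitor pair and 4.61% to 5.17% in the mimic pair. Macrophage transcripts stood out in mimic replicate 2, where Lyz2 (lysozyme) reached 870 CPM against 12.7 to 18.6 CPM in the other 17 libraries and the colony-stimulating factor receptor Csf1r 53.1 CPM against 0.482 to 1.35 CPM.

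High glucose was compared with vehicle to ask what glucose did without a miR-200a-3p reagent. The lists of cell division in the G2 and M phase and of NF-kB inflammation were higher in high glucose, and single genes such as Lamb3, the keratins Krt14 and Krt16 and the interferon-induced Mx1 were lower. Lamb3, a laminin chain of the epithelial basement membrane, fell from 97.3 ± 2.30 CPM in vehicle to 16.3 ± 0.790 CPM (SD, n = 3). The myosin gene Myh3, which encodes the embryonic skeletal heavy chain, rose from 16.3 ± 0.825 to 38.9 ± 4.6 CPM. Of 15074 genes tested, 3652 were called, 1811 higher and 1841 lower, with a median size of 0.32 on the log2 scale among called genes. At least 2-fold changes were seen in 50 genes higher and 165 lower.

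Among the genes that rose, Myh3 (ENSMUSG00000020908.15, chromosome 11, 66969126 to 66993117, + strand) changed by 1.26 ± 0.109 (log2 fold change ± SE, adjusted p = 7.14e-08). The sphingolipid synthase gene Samd8 rose by 1.13 ± 0.0596 (adjusted p = 1.34e-10) and the cell cycle repressor E2f4 by 1.03 ± 0.0507 (adjusted p = 6.12e-11). The cytokines Lif (1.01 ± 0.0790, adjusted p = 1.95e-08) and Il6 (1.0 ± 0.0937, adjusted p = 2.15e-07) rose, Lif from 15.5 ± 0.321 to 31.3 ± 0.339 CPM and Il6 from 24.6 ± 3.83 to 49.1 ± 3.46 CPM. The mitochondrially encoded mt-Nd6 rose by 1.26 ± 0.306 (adjusted p = 0.00466), with 227 ± 90.3 CPM in high glucose. It lies opposite other mitochondrial transcripts, so its reads are uncertain without a known strand setting. Also higher were Prr11 (1.17), Stmn4 (1.07), Kbtbd4 (1.07), Rabl3 (1.05), Dmwd (1.01) and Aktip (0.99).

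Lamb3 (ENSMUSG00000026639.19, chromosome 1, 192890007 to 193027705, + strand) fell by 2.58 on the log2 scale (SE 0.0639, adjusted p = 8.23e-16). The interferon-induced GTPase Mx1 fell by 2.55 (SE 0.258, adjusted p = 5.36e-07), from 11.3 ± 0.344 to 1.94 ± 0.281 CPM. The lysyl oxidase family gene Loxl4 changed by -1.99 ± 0.0646 (adjusted p = 6.28e-14), the retinol dehydrogenase gene Dhrs9 by -1.64 ± 0.0541 (adjusted p = 6.28e-14) and the basal keratin Krt14 by -1.65 ± 0.0993 (adjusted p = 6.60e-10). Isx (-2.58), Tinagl1 (-2.56), Sprr1a (-2.51), Fam167a (-1.84), Krt16 (-1.71) and Atg9b (-1.66) were lower too. Ceacam1, a cell adhesion gene, changed by -1.61 ± 0.466 (adjusted p = 0.0157). Its call ended without vehicle replicate 1 (adjusted p = 0.0537), high glucose replicate 1 (0.0688) or high glucose replicate 2 (0.0501), in a range of 3.53e-12 to 0.0688 over 17 alternatives.

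Of the genes fixed for miR-200a-3p and for cardiac stress, Zeb1 (ENSMUSG00000024238.16, chromosome 18, 5591851 to 5775467, + strand) rose by 0.81 ± 0.0614 (adjusted p = 1.36e-08), from 79.8 ± 5.59 to 140 ± 9.54 CPM. Zeb2 rose by 0.97 ± 0.0664 (adjusted p = 4.55e-09), from 141 ± 12.1 to 276 ± 28.1 CPM. Keap1, the adaptor that leads the oxidative stress factor Nrf2 to degradation, changed by -0.20 ± 0.0640 (adjusted p = 0.0295). The Keap1 call ended without vehicle replicate 3 (adjusted p = 0.189), without high glucose replicate 3 (0.199), with the compared groups alone (0.10) and with GC content and length corrected (0.130), over a range of 0.0125 to 0.199. Ctnnb1, which encodes beta-catenin, differed by 0.09 (adjusted p = 0.274). Txnip, the thioredoxin-interacting protein gene that glucose induces in many cells, lay at 417 ± 9.20 CPM in high glucose and 386 ± 16.8 CPM in vehicle (log2 fold change 0.11 ± 0.113, adjusted p = 0.539). Nppb, the brain natriuretic peptide gene, fell by 2.49 (SE 0.282, adjusted p = 1.98e-06) at low levels of 0.646 ± 0.0164 and 0.111 ± 0.0523 CPM. Myh7 differed by 0.57 (adjusted p = 0.431) at 0.164 and 0.246 CPM.

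By gene list, 19 of 20 G2 and M phase genes rose and 0 fell, with a median of 0.63 (20 higher adjusted over the list alone, camera adjusted p = 9.26e-24, adjusted p = 0.00743 with an estimated correlation). They included Nusap1 (0.95), Cenpf (0.85), the proliferation marker Mki67 (0.82) and the spindle motor Kif11 (0.82). Of 17 genes of NF-kB inflammation, 10 rose and 0 fell (median 0.47; 10 adjusted over the list alone; camera adjusted p = 4.04e-11, 0.00743 with an estimated correlation), with Lif, Il6, the prostaglandin synthase Ptgs2 (0.92) and the chemokine Cxcl1 (0.88). Of 13 published miR-200a targets, 7 rose and 2 fell, also adjusted over the list alone (median 0.25, camera adjusted p = 1.36e-06, 0.0158 with an estimated correlation). Zeb2, Mapk14 (0.88), Klf12 (0.88) and Zeb1 were higher, and Egfr (-0.22) and Keap1 lower. The search of canonical 3′ UTRs found no miR-200a-3p site in Zeb2, Mapk14 or Keap1, and found sites in Klf12, Zeb1 and Egfr. The Mapk14 3′ UTR searched was only 173 nt long, against 972 nt for Keap1 and 2454 nt for Zeb2. A site in a longer form of these UTRs would be missed.

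Other lists passed camera with the preset correlation alone. Of 20 S phase genes 9 rose and 0 fell, or 10 adjusted over the list alone (median 0.13, camera adjusted p = 0.00776), with Cdc6 (0.65), Mcm7 (0.56), Ccne2 (0.46) and Mcm5 (0.41). Of 20 ATF4 stress genes 2 rose and 8 fell, or 9 fell adjusted over the list alone (median -0.11, camera adjusted p = 0.000866). Chac1 (-1.13), Trib3 (-1.03) and Atf3 (-0.70) were lower and the serine pathway enzyme Shmt2 (0.73) higher. Of 24 interferon response genes 0 rose and 5 fell, or 6 adjusted over the list alone (median -0.23, camera adjusted p = 0.000955), with Mx1, Oas3 (-1.09), Usp18 (-0.85) and Oasl2 (-0.73). For each of these 3 lists the adjusted p was 0.559 with an estimated correlation. Of 33 ribosomal protein genes 0 rose and 7 fell, also adjusted over the list alone (median -0.10, camera adjusted p = 0.0306), among them Rpl27 (-0.27). That call had an adjusted p of 0.906 with an estimated correlation and 0.0504 without mimic replicate 2, over a range of 0.0210 to 0.0504 in 5 other settings.

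Not past the list test were cardiac contractile genes (median 0.10, 6 higher and 3 lower, camera adjusted p = 0.531), the fetal gene program of hypertrophy (-0.20, 1 higher and 5 lower, 0.256), glycolysis (-0.09, 2 higher and 7 lower, 0.256), glucose-responsive genes (-0.10, 1 higher and 2 lower, 0.795) and Nrf2 targets (0.08, 4 higher and 4 lower, 0.691). Mesenchymal genes had a median of 0.08 (camera adjusted p = 0.0781) and epithelial genes one of -0.23 (0.0781). With GC content and length corrected these became 0.0117 and 0.0258, and 0.477 and 0.243 with an estimated correlation. Mitochondrially encoded genes (-0.30, 1 higher and 5 lower, 0.220) became 0.0168 with that correction, and 0.539 with an estimated correlation. Macrophage markers had a median of 0.03, with 0 of 9 called (0.924).

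Genes with a site for miR-200a-3p in the 3′ UTR were examined here after the mimic and inhibitor results had been seen. Of 684 genes with an 8mer site, 242 (35.4%) rose in high glucose and 43 (6.29%) fell, against 896 (9.60%) and 1406 (15.1%) of 9330 genes with no site. The median of genes with any site lay 0.09 above that of genes with none, and for 8mer sites 0.17, both above all 419 shuffled words, whose highest values were 0.07 and 0.14. camera gave p = 7.79e-10 for 8mer sites (p = 0.0107 with an estimated correlation) and p = 3.28e-05 for any site (p = 0.0375 with an estimated correlation). Of all 14444 words of 7 bases, the seed match CAGTGTT, present in 2868 genes, had the largest positive slope statistic. Examples with the 8mer CAGTGTTA were Kbtbd4 (chromosome 2, 90740501 to 90740508, + strand, 3′ UTR in exon 4 of 4), Dmwd (chromosome 7, 18816478 to 18816485, + strand, exon 4 of 4), the kinase gene Cdk19 (0.95; chromosome 10, 40357863 to 40357870, + strand, exon 13 of 13) and the alarmin Il33 (0.92; chromosome 19, 29938699 to 29938706, + strand, exon 8 of 8).

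**Figure D2:**
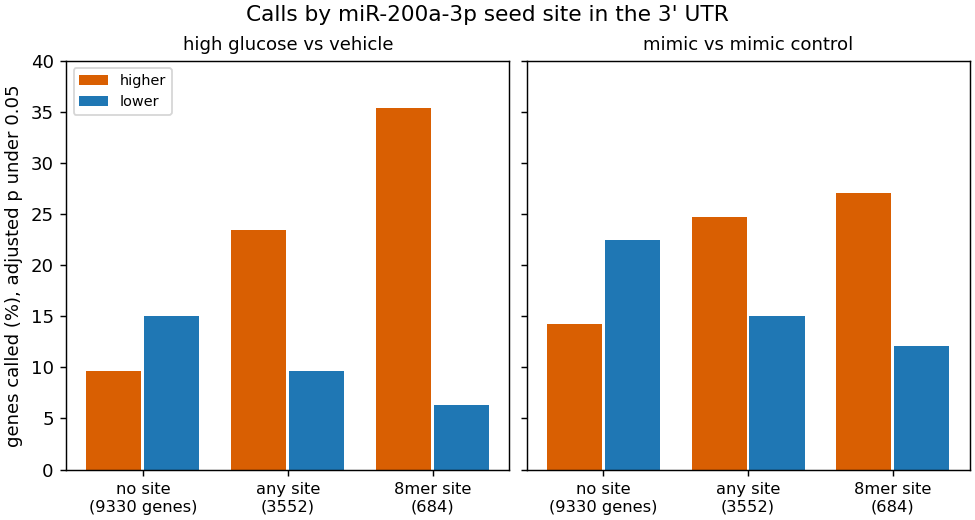
Share of genes called higher or lower (percent, y axis) by the miR-200a-3p site in the 3′ UTR (none 9330 genes, any 3552, 8mer 684), in high glucose against vehicle and in mimic against mimic control. In high glucose 35.4% of genes with an 8mer site were higher against 9.60% with none, and in the mimic comparison 12.1% were lower against 22.5%.

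The mimic was compared with its negative control, both in high glucose, to ask which genes added miR-200a-3p moved. The level of miR-200a-3p in the cells and the uptake of the mimic are not measured by these mRNA libraries. The muscle filamin Flnc, the iron-binding secreted protein Lcn2 and the laminin chains Lama3 and Lamb3 were lower with the mimic, and the nuclear RNA Xist was higher. S phase genes passed lower and Nrf2 targets higher as lists, and neither held with an estimated correlation (adjusted p = 0.390 for both). Flnc, a sarcomere-linked actin cross-linker, fell from 2269 ± 65.5 to 1293 ± 39.3 CPM (SD, n = 3). Xist, which silences an X chromosome, rose from 118 ± 2.24 to 254 ± 8.40 CPM. Xist differed more between groups without the mimic. It lay at 35.7 to 49.1 CPM in vehicle, 19.1 to 37.9 CPM in high glucose and 1058 to 1231 CPM in the inhibitor group and its control. The microRNA's known target Zeb1 lay at 42.4 CPM with the mimic against 43.9 CPM in the mimic control. In all, 5087 genes were called, 2375 (46.7%) higher and 2712 lower. The share higher was 38.9% with GC content and length corrected, 39.6% in DESeq2, 41.1% with DESeq2 size factors, 55.1% with upper quartile scaling and 61.3% and 63.5% with limma on FPKM.

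Most of the genes that rose by the largest amounts did so through mimic replicate 2, the library with macrophage transcripts. Slfn2 (3.64, adjusted p = 0.00337) had 8.76 ± 13.6 CPM against 0.701 CPM in the control, and without that replicate its change was 0.34. Without it the changes of the complement gene Cfb (3.23), Cd93 (2.76), Rassf2 (2.61) and the cytokine receptor Csf2rb (2.30) were 0.21, 0.48, 0.47 and 0.45, and none of these genes was called. Alox5ap (2.42), Neat1 (2.29), Cyp4v3 (1.51) and Evi2 (1.12) were still called at 0.59, 0.85, 0.40 and 0.53. The Cyp4v3 call ended with the compared groups alone (adjusted p = 0.0625) and in limma on log2(FPKM + 1) (0.0604), in a range of 1.50e-22 to 0.0625, and that of Alox5ap in limma on log2(FPKM + 1) (0.0521, from 1.71e-76). The calls of Slfn2, Cfb, Cd93, Rassf2 and Csf2rb also ended with the compared groups alone and in limma on FPKM with either pseudocount, with highest values of 0.343, 0.568, 0.106, 0.120 and 0.131. Xist (ENSMUSG00000086503.5, chromosome X, 102503972 to 102537573, - strand) rose by 1.10 ± 0.146 (adjusted p = 2.62e-05) and by 1.10 without replicate 2. Srp54a rose by 1.23, or 1.48 without replicate 2, but has near-identical copies, so its reads are uncertain. By the same rule without replicate 2, chosen after seeing the data, Malat1 (0.90), Spaca6 (0.81), mt-Rnr2 (0.73), the pyruvate dehydrogenase kinase Pdk1 (0.71), Lrrcc1 (0.70), Mfap3l (0.70), the cystine transporter Slc7a11 (0.70), the bone morphogenetic protein antagonist Grem1 (0.68) and Gnpda2 (0.67) were also named. Without it 4011 genes were called, 1734 higher and 2277 lower, of which 3793 were also called with it and 7 of those in the opposite direction.

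The genes that fell most did not rest on that library. Lcn2 changed by -1.53 ± 0.192 (adjusted p = 1.50e-05), from 8.03 ± 0.373 to 2.78 ± 0.322 CPM, the clock repressor Nr1d1 by -0.83 ± 0.0825 (adjusted p = 1.61e-06), from 78.7 ± 7.58 to 44.3 ± 2.22 CPM, and Flnc (chromosome 6, 29433072 to 29461887, + strand) by -0.81 ± 0.0546 (adjusted p = 7.07e-08). The laminin chains Lama3 (-0.81) and Lamb3 (-0.80 ± 0.0734, adjusted p = 7.77e-07), plakoglobin (Jup, -0.80) and the myofibril gene Nrap (-0.79) fell too, as did Tinagl1 (-0.86), Adgrg1 (-0.82), Angptl4 (-0.74), Eps8l2 (-0.72) and Gprc5a (-0.71). Without replicate 2 the rule also named Fat1 (-0.73) and the protease gene Adam8 (-0.74), which had stood at 0.25 with all libraries.

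Among the fixed genes, Zeb2 rose by 0.58 ± 0.0656 (adjusted p = 5.61e-06), from 242 ± 5.51 to 361 ± 17 CPM. Zeb1 differed by -0.05 (adjusted p = 0.593), and with GC content and length corrected by -0.15 (adjusted p = 0.0471, in a range of 0.0471 to 0.933). Keap1 (-0.04, adjusted p = 0.711), Ctnnb1 (-0.00, 0.982), Txnip (0.45, 0.403), Nppb (-0.35, 0.123) and Myh7 (-0.16, 0.846) were not called. Txnip lay at 1.07 CPM with the mimic and 0.785 CPM with its control.

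Genes with a miR-200a-3p site did not lie lower with the mimic than the shuffled words. The median of 3552 genes with any site was 0.09 above that of genes with none, and 300 of 419 shuffled words gave a value as low. For 8mer sites it was 0.10, with 221 of 419 words as low, and 12.1% of these genes fell against 22.5% with no site. camera placed genes with any site higher (p = 0.00175, p = 0.101 with an estimated correlation), and the seed match ranked 3151 of 14444 words from the lowest, or 11018 without mimic replicate 2, where its slope turned from -0.0121 to 0.00875. Of 13 published targets 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.606). Zeb2 and Sirt1 (0.45) were higher and Egfr (-0.30) and Elmo2 (-0.24) lower. In the canonical 3′ UTRs searched, Zeb2 and Elmo2 had no site, and Sirt1 and Egfr had one. The list's median was -0.00, its mean 0.05 and its test upward.

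Genes with an 8mer in the 3′ UTR met the rule among those that fell. Tbl3, a small-subunit ribosome assembly factor, changed by -0.57 ± 0.0570 (adjusted p = 1.61e-06), from 92.0 ± 2.87 to 61.8 ± 2.93 CPM; its site lies on chromosome 17, 24917579 to 24917586, - strand, in exon 22 of 22. The ephrin receptor Epha2 changed by -0.57 ± 0.0529 (chromosome 4, 141056560 to 141056567, + strand, exon 17 of 17), the replication helicase gene Mcm5 by -0.49 (chromosome 8, 75855326 to 75855333, + strand, exon 17 of 17) and the retinoic acid hydroxylase gene Cyp26b1 by -0.49 (chromosome 6, 84551001 to 84551008, - strand, exon 6 of 6). The spliceosome helicase gene Snrnp200 changed by -0.42 (chromosome 2, 127082996 to 127083003, + strand, exon 45 of 45).

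By gene list, 11 of 20 Nrf2 targets rose and 3 fell with the mimic, also adjusted over the list alone (median 0.22, camera adjusted p = 9.81e-05, adjusted p = 0.390 with an estimated correlation). Slc7a11 (0.68), the glutathione synthesis subunit Gclm (0.61), the quinone reductase Nqo1 (0.57) and Srxn1 (0.54) led it. Of 20 S phase genes 1 rose and 12 fell, also adjusted over the list alone (median -0.21, camera adjusted p = 5.02e-05, adjusted p = 0.390 with an estimated correlation), with Mcm5, Mcm2 (-0.42) and Mcm3 (-0.41) lower and Ccne2 (0.49) higher. In the fetal gene program of hypertrophy 0 of 9 rose and 4 fell, also over the list alone (median -0.33, camera adjusted p = 0.0115, adjusted p = 0.390 with an estimated correlation). These were skeletal actin Acta1 (-1.39), Xirp1 (-1.09), smooth muscle actin Acta2 (-0.44) and the calcineurin regulator Rcan1 (-0.33).

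Metabolic and stress lists passed downward with the preset correlation alone. Of 19 glycolysis genes 1 rose (Pdk1, 0.69) and 9 fell, or 12 fell adjusted over the list alone (median -0.19, camera adjusted p = 0.00202, adjusted p = 0.635 with an estimated correlation), with Hk1 (-0.40), Slc16a3 (-0.30) and Pfkp (-0.30). Of 20 ATF4 stress genes 1 rose and 12 fell, also over the list alone (median -0.25, camera adjusted p = 0.00202, adjusted p = 0.620 with an estimated correlation), among them Slc3a2 (-0.44), Sesn2 (-0.41) and Atf5 (-0.39), while Slc7a11 was higher. Of 30 nuclear genes of oxidative phosphorylation 1 rose and 11 fell, or 15 over the list alone (median -0.11, camera adjusted p = 0.0115, adjusted p = 0.620 with an estimated correlation), led by Uqcrc1 (-0.44) and Ndufv1 (-0.37). Of 16 unfolded protein response genes 0 rose and 7 fell, or 8 adjusted over the list alone (median -0.12, camera adjusted p = 0.0115, adjusted p = 0.620 with an estimated correlation), with Calr (-0.38), Syvn1 (-0.38), Hyou1 (-0.35) and Manf (-0.32). Of 24 matrix genes 2 rose and 11 fell, also over the list alone (median -0.09, camera adjusted p = 0.0115, adjusted p = 0.662 with an estimated correlation). Thbs1 (2.11) was -0.51 without replicate 2, and Col4a2 (-0.54) and Col5a1 (-0.42) were lower. With GC content and length corrected the glycolysis test gave 0.0669 (0.00128 to 0.0669 over 5 settings) and the matrix test 0.362 (0.00284 to 0.362).

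Macrophage markers had a median of 3.83, with 7 of 9 called higher and 8 adjusted over the list alone (camera adjusted p = 0.0561, 0.804 with an estimated correlation), among them Csf1r (4.14), Fcgr3 (4.12), Lyz2 (4.06) and C1qa (3.86). The list passed with GC content and length corrected (0.0149) and with DESeq2 size factors (0.0351), but not with an estimated correlation (0.622 and 0.781), and without replicate 2 its median was -0.18 (0.267, the highest of 5 settings). Interferon genes had a median of -0.04, a mean of 0.31 and an upward test, immediate early genes 0.11, 0.47 and a downward test, and neither passed. Without replicate 2 the median of immediate early genes was -0.23 and the list passed downward (camera adjusted p = 0.0462, adjusted p = 0.596 with an estimated correlation), against up to 0.990 in other settings. The GC content of genes correlated with their change across genes at a Spearman value of -0.47, and genes are not independent replicates. With GC content and length corrected 3841 genes were called, 2957 of them also called without the correction.

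The inhibitor was compared with its negative control, both in high glucose, to ask what blocking miR-200a-3p moved. No single gene passed, and genes of cholesterol synthesis lay slightly lower as a group. edgeR called 0 of 15074 genes, with 447 (2.97%) at an unadjusted p under 0.05. DESeq2 also called 0 (304 unadjusted), and limma on FPKM called 0 with either pseudocount (674 and 542 unadjusted). In the simulated data at this depth, for genes of at least 1 CPM in the control, 90% of 1.5-fold changes and 96% of 2-fold changes were recovered. There 200 genes were changed at once, which makes the adjusted threshold easier to pass. Recovery with few changed genes was not tested and may be lower. The mRNA libraries do not measure the level of miR-200a-3p or the uptake of the inhibitor. The lack of called genes therefore cannot tell an inhibitor that did not act from a block without effect.

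The 4 genes with the smallest p, none of which passed (adjusted p = 1), were Lss, Gtdc1, Gm28439 and Smco3. Lss, the lanosterol synthase of cholesterol synthesis (chromosome 10, 76367298 to 76392976, + strand), lay at 104 ± 3.18 CPM with the inhibitor and 120.5 ± 5.39 CPM with the control (-0.21 ± 0.0475, unadjusted p = 0.000327). Gtdc1 differed by 0.50 (unadjusted p = 0.000409). Gm28439, a predicted gene model on chromosome 1, differed by -1.59 (unadjusted p = 0.000445) with an uneven control at 13.5 ± 11.7 CPM, and Smco3 lay at 0.102 against 0 CPM, near the floor. Without a filter on low counts 26 genes were called, 25 of which had been tested with it, Gm28439 among them at an adjusted p of 1.23e-29 (to 1 in other settings). With the compared groups alone 1 gene was called, the tubulin gene Tuba1b (-0.57, adjusted p = 0.00781), which was named after its values were seen.

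Zeb1 lay at 72.1 ± 1.61 CPM with the inhibitor and 69.8 ± 1.48 CPM with the control (log2 fold change 0.05), and Zeb2 (-0.01), Keap1 (-0.00), Ctnnb1 (0.01), Nppb (-0.20), Myh7 (-0.21) and Txnip (-0.23) differed as little or at low counts. The 13 published targets had a median of 0.02, with 0 called over all genes and adjusted over the list alone (camera adjusted p = 0.349). Genes with any site lay 0.01 above those with none, and 322 of 419 shuffled words gave a value as low (camera p = 0.381, p = 0.630 with an estimated correlation).

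The 22 cholesterol synthesis genes had a median of -0.11 (camera adjusted p = 2.87e-15, adjusted p = 0.000158 with an estimated correlation, fry adjusted p = 0.000448). Of them 0 were called over all genes and 2 were lower adjusted over the list alone, Lss and Hmgcs1 (-0.16). Lists that passed camera with the preset correlation alone had small medians. They were glycolysis (-0.08, adjusted p = 1.67e-07, and 0.439 with an estimated correlation), and, with the values in the same order, G2 and M phase (0.06, 0.000344 and 0.449), S phase (0.06, 0.000381 and 0.439), ATF4 stress (-0.04, 0.00158 and 0.476), hypoxia (-0.04, 0.00537 and 0.476) and matrix genes (-0.03, 0.0274 and 0.657). None of their members was called over all genes. The matrix test gave 0.0797 with GC content and length corrected and 0.215 without mimic replicate 2, over a range of 0.0298 to 0.215 in 5 settings.

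The negative controls were compared with untransfected high glucose cells to show the background the reagents were measured on. With the mimic control, stress genes of the ATF4 pathway and cell division genes were higher, and inflammatory, matrix, cholesterol synthesis and glucose-responsive genes were lower. Txnip (ENSMUSG00000038393.15, chromosome 3, 96465267 to 96469201, + strand) fell from 417 ± 9.20 CPM in high glucose to 0.785 ± 0.164 CPM with the mimic control (SD, n = 3). Of 15074 genes 11891 were called, 5872 higher and 6019 lower. These groups were also separate clusters of libraries, so the control reagent and any difference in handling cannot be told apart.

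Txnip changed by -9.05 ± 0.200 (adjusted p = 4.76e-19). Smtnl1, a smoothelin-like muscle gene, had 0 reads with the mimic control and 6.68 ± 0.280 CPM in high glucose, and Nlrp10 had 0.0391 against 11.9 CPM. Myh3 (-7.63) and Tmem119 (-7.60) were lower too. B4galnt2 had 9.61 ± 0.598 CPM with the control and 0.00902 CPM in high glucose. Try5 (7.88 ± 0.213), the basement membrane collagen Col4a4 (7.51 ± 0.176), the teneurin Tenm2 (7.32 ± 0.112) and the peroxisomal oxidase Acox2 (6.98) were higher. Zeb1 (-1.68) and Keap1 (-0.91) fell and Nppb (4.25) rose. Zeb2 (-0.19, adjusted p = 0.0114) lost its call without high glucose replicate 3 (0.102) or mimic control replicate 3 (0.0508) and with GC content and length corrected (0.0782), from a range of 0.000374 to 0.102. Ctnnb1 (0.17, adjusted p = 0.00744) lost it without high glucose replicate 1 (0.0619) and at 0.00 on FPKM (0.954 and 0.951), from 0.000248 up. Myh7 (-0.41, adjusted p = 0.433) was not called.

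List counts of the mimic control were the same adjusted over the list alone. Of 20 ATF4 genes 17 rose and 2 fell (median 2.14, camera adjusted p = 4.52e-18, 0.00757 with an estimated correlation), with Trib3 (4.33), the stress factor Ddit3 (4.20), Atf3 (3.92) and Chac1 (3.85). In the same order of median, camera adjusted p and adjusted p with an estimated correlation, all 20 G2 and M phase genes rose (2.14, 8.20e-16 and 0.0122) and 18 of 20 S phase genes rose (1.70, 2.13e-16 and 0.00757), led by Mcm5 (4.44) and Mcm3 (4.44). Of 17 NF-kB genes 1 rose and 15 fell (-3.71, 3.93e-11 and 0.00710), with Cxcl1 (-5.65), Ccl2 (-5.25), Cxcl5 (-5.23) and Il6 (-4.94). Of 24 matrix genes 0 rose and 23 fell (-1.62, 2.25e-18 and 0.00757), with the collagens Col6a1 (-5.86) and Col6a2 (-5.63). Of 22 cholesterol synthesis genes 1 rose and 20 fell (-2.05, 4.42e-10 and 0.00204), with Fdps (-3.45). Of 13 glucose-responsive genes 2 rose and 11 fell (-1.95, 0.000366 and 0.00757), with Txnip, its homologue Arrdc4 (-4.29 ± 0.341), Acacb (-3.23) and Pdk4 (-3.03). Fibroblast markers fell in 6 of 8 and rose in 1 (-2.48, 1.88e-07 and 0.00757), with Dpt (-7.58) and Pdgfra (-3.98).

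With an estimated correlation the unfolded protein response (median 1.07, 14 higher and 1 lower, camera adjusted p = 2.02e-05) had an adjusted p of 0.0796. The chaperone Hspa5 rose by 2.20 and Sdf2l1 by 2.44 in it. Ribosomal protein genes (0.90, 33 of 33 higher, 1.75e-07) had 0.308, mesenchymal genes (-1.23, 2 higher and 11 lower, 0.000947) 0.0796 and cardiac contractile genes (-1.84, 2 higher and 12 lower, 0.00556) 0.156 with an estimated correlation, with titin (Ttn) at -6.27. Insulin signalling genes (-0.34, 6 higher and 10 lower, 0.0319) had an adjusted p of 0.354 with an estimated correlation, 0.170 with GC content and length corrected and 0.0510 without mimic replicate 2, in a range of 0.0279 to 0.170.

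**Figure D3:**
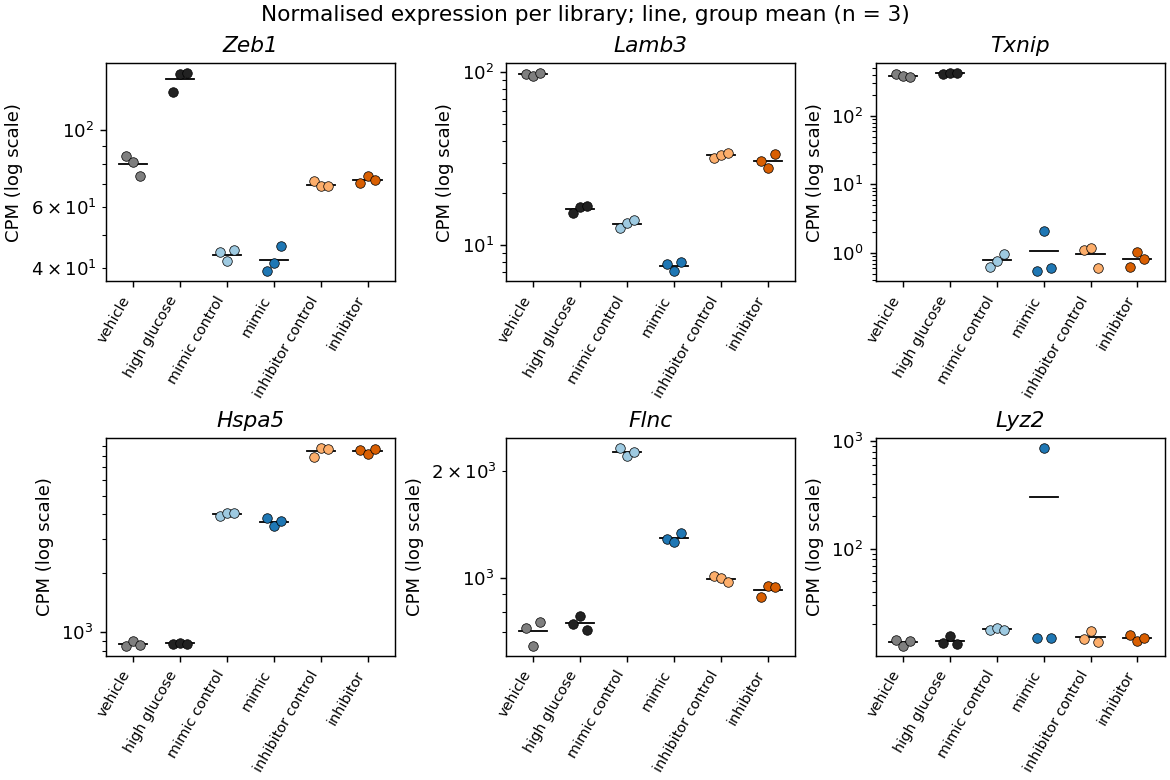
CPM scaled by TMM (log axis) of Zeb1, Lamb3, Txnip, Hspa5, Flnc and Lyz2, 1 point per library and a line at the mean of 3 libraries per group. Txnip lay at 417 CPM in high glucose and 0.785 CPM with the mimic control, and Lyz2 reached 870 CPM in mimic replicate 2.

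With the inhibitor control, endoplasmic reticulum chaperones, ATF4 genes and cell division genes were higher than in untransfected high glucose cells, and inflammatory, matrix and fibroblast genes were lower. Txnip fell to 0.961 ± 0.309 CPM and the chemokine Cxcl1 from 648 to 4.34 CPM. In all 11977 genes were called, 6049 higher and 5928 lower. H2-M10.1, a non-classical major histocompatibility gene, rose from 0.325 to 57.6 ± 2.61 CPM (7.44 ± 0.136). The low share of Rn18s reads in the inhibitor pair went with this contrast.

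Txnip changed by -8.75 ± 0.193 (adjusted p = 9.30e-19), Cxcl1 by -7.22 ± 0.126, Il6 by -7.01, Rdh16f1 by -6.94 and mt-Rnr1 by -5.45. Try5 (7.27), Acox2 (6.73) and Col4a4 (6.72) were higher, and Dok7 lay at 5.09 against 0.0281 CPM. Zeb1 (-1.01) fell and Zeb2 (0.49) and Nppb (4.64) rose. Keap1 (-0.56) was 0.02 with GC content and length corrected. Myh7 (1.0, adjusted p = 0.0276) lost its call without high glucose replicate 1 (0.0939), high glucose replicate 3 (0.142) or inhibitor control replicate 1 (0.143), in DESeq2 (0.110) and in limma on log2(FPKM + 1) (0.0629), from a lowest value of 0.00174. Ctnnb1 (-0.04, adjusted p = 0.550) was not called.

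All 16 unfolded protein response genes rose with the inhibitor control (median 2.53, camera adjusted p = 9.68e-28, 0.000944 with an estimated correlation), with Sdf2l1 (4.35), Hspa5 (3.27), Hsp90b1 (3.14) and Herpud1 (3.03). Counts of these lists were the same adjusted over the list alone. In the same order of median, camera adjusted p and adjusted p with an estimated correlation, of 20 ATF4 genes 17 rose and 2 fell (1.67, 3.05e-18 and 0.0121), and all 20 G2 and M phase genes rose (2.12, 1.07e-17 and 0.0130). Of 17 NF-kB genes 0 rose and 15 fell (-3.91, 1.21e-16 and 0.000944). Of 24 matrix genes 1 rose and 21 fell (-1.47, 5.52e-16 and 0.0163), of 8 fibroblast markers 0 rose and 6 fell (-2.29, 1.09e-07 and 0.0121), and of 13 mesenchymal genes 4 rose and 9 fell (-1.01, 0.000290 and 0.0487). Ferroptosis genes rose in 9 and fell in 6 of 15 (0.45, 0.00280 and 0.0163), with a median of -0.09 and 0.0719 with an estimated correlation once GC content and length were corrected.

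Lists that held with the preset correlation alone were interferon response (median 1.32, 21 higher and 2 lower, camera adjusted p = 0.00302, adjusted p = 0.341 with an estimated correlation), with Usp18 (4.83) and Ifi44 (4.83), and, in the same order, p53 targets (-0.73, 3 higher and 15 lower, 0.00450 and 0.0923). The same held for hypoxia (0.87, 12 higher and 4 lower, 0.00740 and 0.298), insulin signalling (-0.35, 4 higher and 11 lower, 0.00757 and 0.296) and ribosomal proteins (0.31, 28 higher and 0 lower, 0.0144 and 0.569). Immediate early genes (-1.60, 4 higher and 14 lower, 0.0393 and 0.459) gave 0.167 with GC content and length corrected, in a range of 3.5e-05 to 0.167 over 5 settings. Glucose-responsive genes (-0.45, 4 higher and 7 lower) did not pass (camera adjusted p = 0.368), except without mimic replicate 2 (0.0378, 0.0851 with an estimated correlation), in a range of 0.0378 to 0.714.

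The negative controls were compared with each other to ask whether they gave 1 background. Cholesterol synthesis and chaperone genes were higher with the inhibitor control, and replication genes and Rn18s were lower. Interferon genes were higher too, but that list did not hold with an estimated correlation (adjusted p = 0.0752). The giant sarcomere protein gene Ttn lay at 27.9 CPM with the inhibitor control and 0.111 CPM with the mimic control (7.92 ± 0.209), and the calcification inhibitor Mgp at 88.4 and 0.627 CPM (7.13 ± 0.111). In all 11181 genes were called, 5796 higher and 5385 lower. Upper quartile scaling moved the median of all genes by 0.105, from 0.04 to 0.15.

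Spon2 (6.28), the basement membrane gene Nid2 (6.05) and Dnm3os (5.89) were higher too. Lower were Morc1 (-3.71), Rn18s (-3.33 ± 0.182, 1017 ± 271 against 10255 ± 1011 CPM), Rhov (-3.27), Lcn2 (-3.23) and Nr1d1 (-3.19, 8.60 against 78.7 CPM). Zeb1 (0.67), Zeb2 (0.68), Keap1 (0.35) and Myh7 (1.41, adjusted p = 0.00553) were higher and Txnip (0.30, adjusted p = 0.501) was not called. Ctnnb1 (-0.20, adjusted p = 0.00196) lost its call with upper quartile scaling (0.0866) and on FPKM (0.306 and 0.30), from a lowest value of 0.000139. Nppb (0.39, adjusted p = 0.0389) lost it in 8 of 17 alternatives, with a highest value of 0.209. These were DESeq2, no filter, the GC and length correction, and leaving out any inhibitor control library or mimic control replicate 1 or 2.

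All 22 cholesterol synthesis genes were higher with the inhibitor control (median 1.53, camera adjusted p = 3.43e-28, 8.63e-06 with an estimated correlation), with Fdps (4.07), Idi1 (3.51) and Insig1 (3.08). In the same order of median, camera adjusted p and adjusted p with an estimated correlation, all 20 S phase genes were lower (-1.50, 4.01e-25 and 0.00247), all 16 unfolded protein response genes higher (1.19, 1.37e-17 and 0.00364), and of 13 glucose-responsive genes 7 were higher and 2 lower (0.48, 3.02e-05 and 0.00364), with Pdk4 at 3.06. Counts were the same adjusted over the list alone for these 4 lists. Lost with an estimated correlation were interferon genes (median 2.38, 23 of 24 higher and 24 over the list alone, camera adjusted p = 9.01e-11, adjusted p = 0.0752 with an estimated correlation), hypoxia (0.58, 17 higher and 1 lower, 3.02e-05 and 0.148), ribosomal proteins (-0.54, 1 higher and 30 lower, or 2 higher over the list alone, 1.28e-05 and 0.425), nuclear oxidative phosphorylation (-0.48, 2 higher and 25 lower, 5.37e-05 and 0.183) and p53 targets (-0.58, 3 higher and 14 lower, 0.00174 and 0.0916). The same held for matrix genes (0.47, 13 higher and 7 lower, 0.00211 and 0.415), cardiac contractile genes (1.30, 10 higher and 1 lower, 0.00250 and 0.183) and smooth muscle markers (0.88, 4 higher and 2 lower, or 5 higher over the list alone, 0.0143 and 0.232). Mitochondrially encoded genes (1.16, 11 of 12 higher, 0.00211 and 0.211) had a median of 0.03 and a camera adjusted p of 0.506 with GC content and length corrected, in a range of 0.00186 to 0.506.

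The effect of the mimic was set against that of the inhibitor in 1 test of their difference. The inhibitor comparison had called 0 genes on its own, so a difference here need not involve an effect of the inhibitor. The muscle genes Xirp1, Xirp2 and Nrap were lower with the mimic relative to the inhibitor, and Zeb2 was higher. S phase genes passed lower and Nrf2 targets higher as lists, and neither held with an estimated correlation (adjusted p = 0.297 for both). Zeb2 differed by 0.59 (adjusted p = 0.000859), Nrap by -0.91 (adjusted p = 0.000133), the actin-binding Xirp2 by -1.11 (0.00221), Xirp1 by -1.09 (0.00323), Atg9b by -1.30 (0.000447) and Lcn2 by -1.36 (0.00867). Of 15074 genes 1993 were called, 698 (35.0%) higher and 1295 lower, and the share higher was 47.2% with upper quartile scaling, 46.7% with no filter and 49.5% and 53.1% with limma on FPKM. It was lower with DESeq2 size factors (27.7%), with GC content and length corrected (28.2%), in DESeq2 (29.2%) and without inhibitor control replicate 3 (25.6%, 319 genes higher). Xirp1 lost its call in limma on log2(FPKM + 1) (0.0567, in a range of 5.29e-05 to 0.0567).

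The 5 genes higher by the rule were Rassf2 (2.70), Ccl9 (2.51), Csf2rb (2.43), Cebpa (2.38) and Alox5ap (2.37), with adjusted p-values of 0.0299 to 0.0485. Their differences were 0.57, 0.82, 0.58, 0.69 and 0.55 without mimic replicate 2, where none was called. Leaving out any inhibitor, inhibitor control or mimic control library also ended these calls, except that of Ccl9 without inhibitor control replicate 1. All 5 calls also ended with the compared groups alone and in limma on FPKM with either pseudocount, with highest values of 0.250 (Alox5ap) to 0.356 (Ccl9). The replicate block ended those of Rassf2 (0.0595), Csf2rb (0.0642) and Alox5ap (0.0607), and the correction for GC content and length those of Rassf2 (0.0565) and Alox5ap (0.0689). Zeb1 (-0.10, adjusted p = 0.512), Keap1 (-0.04, 0.845), Ctnnb1 (-0.01, 0.960), Txnip (0.68, 0.430), Nppb (-0.15) and Myh7 (0.05) were not called.

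By list, 11 of 33 passed camera and 0 with an estimated correlation. S phase genes had 0 higher and 12 lower, or 1 and 12 adjusted over the list alone (median -0.29, camera adjusted p = 2.19e-07, adjusted p = 0.297 with an estimated correlation). With the values in that order, Nrf2 targets had 8 higher and 2 lower, or 9 and 2 adjusted over the list alone (0.16, 0.000718 and 0.297). The unfolded protein response (-0.15, 0.00169 and 0.346) had 4 lower, the fetal gene program (-0.15, 0.00799 and 0.297) 3 and nuclear oxidative phosphorylation (-0.10, 0.00799 and 0.604) 5, which were 6, 4 and 5 adjusted over the list alone. Hypoxia (0.13, 0.0366 and 0.742) had 4 higher and 1 lower, or 6 and 2 over the list alone. Macrophage markers (3.40, 0.0291 and 0.742) had 0 members called, or 2 higher adjusted over the list alone, and a median of -0.24 and a camera adjusted p of 0.338 without mimic replicate 2, in a range of 0.00617 to 0.338. The other 4 lists that passed each lost the call in at least 1 of 5 settings. They were G2 and M phase (-0.11, 0.0291 and 0.742; highest camera value 0.0749), cholesterol synthesis (0.08, 0.0379 and 0.297; 0.0541), ATF4 stress (-0.18, 0.0379 and 0.742; 0.471) and smooth muscle markers (-0.16, 0.0470 and 0.604; 0.230).

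Across genes, the changes of comparisons that share no library were set side by side. High glucose and the mimic correlated at 0.04 (Pearson) and 0.16 (Spearman), high glucose and the inhibitor at -0.01 and 0.04, and the mimic and the inhibitor at 0.02 and 0.09. With GC content and length corrected, high glucose and the mimic correlated at 0.00312 and 0.0592. Without it, changes followed the GC content of genes at Spearman values of -0.22 for high glucose and -0.47 for the mimic. Genes are not independent replicates, so no p is given. Of the genes called in both the high glucose and the mimic comparison, 561 were higher in both (285 for independent lists), 616 lower in both (331), 261 higher with glucose and lower with the mimic (326), and 150 the reverse (290). These counts are without the correction for GC content and length.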

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

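The fit without mimic replicate 2 in any comparison, the correction for GC content and length and the regroupings within pairs were tests chosen after the result was seen. The effects of mimic and inhibitor, each against its own negative control, differed in 1993 genes by edgeR's test of the difference. That count was 1582 without mimic replicate 2 and 1541 with GC content and length corrected. On its own the inhibitor comparison called 0 genes and the mimic comparison 5087. The difference therefore does not show that the inhibitor moved genes or acted against the mimic. Among 40 groupings of the 12 transfected libraries, the real one included, 6 gave as many genes. The highest other count was 9439, and chance is not excluded by this share. A regrouping that calls several times the real number points to a structure of the samples. Libraries of the inhibitor pair correlated with those of the mimic pair at 0.950 to 0.963 against 0.980 to 0.996 within the pairs, so regroupings across pairs bring that difference in and are a poor measure of chance. With each library kept in its pair 3 of 40 groupings, the real one included, gave as many genes (highest other 3307), by which chance is not excluded either. All 3 kept the mimic libraries apart from their control, and the others gave 0. These 3 hold the mimic contrast, as it stands or mirrored, and so do not measure chance in it. No biological explanation of the count was tested.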

How the results depend on the processing

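The correction for GC content and length, the fits without mimic replicate 2 and other scalings of the gene lists were chosen after the results were seen. Counts of genes called at any fold stayed within 1.5 times under other scalings, filters and tools except as given here. A 2-fold minimum left 215 genes for high glucose, 376 for the mimic, 5954 and 5428 for the mimic and inhibitor controls against high glucose, 3895 between the controls and 77 for the difference of effects, since fewer genes qualify. Without mimic replicate 2 the mimic count was 86 (52 higher and 34 lower) and that of the difference 47, against 288 and 268 without mimic replicates 1 and 3. The difference had 44 to 51 without inhibitor replicate 1, inhibitor control replicate 2 or 3, or mimic control replicate 1 or 3. For high glucose, mimic and difference, DESeq2 gave 119, 234 and 23 and limma 20, 4 and 2 on log2(FPKM + 1) and 101, 29 and 22 on log2(FPKM + 0.1). Without a filter the mimic had 657 and the difference 478, with the 1 CPM filter high glucose had 136 and the mimic 211, with the compared groups alone the mimic had 68, and with GC content and length corrected the difference had 50. On log2(FPKM + 1) the control comparisons had 2888, 2293 and 1090. The inhibitor comparison called 26 genes without a filter and 1 with its groups alone; the cause was not tested. Leaving out 1 library gave 1244 to 2207 genes for the difference of effects, with 1304 without inhibitor control replicate 2, 1244 without inhibitor control replicate 3 and 1286 without mimic control replicate 1. Of 73 list calls in all comparisons, 24 held with an estimated correlation, while fry called 122 one way and 183 in either direction, and neither fry test compares a list with other genes. The shift of site genes with the mimic was 0.09, 0.04 (0.0393) against genes matched on UTR length and expression and 0.01 (0.0135) after the median of shuffled words was taken off. By construction, matching removes what UTR length and expression bring, and subtraction what words of the same bases bring.

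Single genes turned direction in few settings. With GC content and length corrected Keap1 went from -0.56 to 0.0248 and mt-Atp8 from 1.52 to -0.91 in the inhibitor control comparison, and mt-Nd5 from 0.25 to -0.10 with the mimic; the cause was not tested. Without mimic replicate 2, the library with macrophage transcripts, the changes with the mimic went from 3.74 to -0.40 for Cd36, 2.64 to -0.0321 for Nlrp3, 3.87 to -0.93 for Il1a, 2.11 to -0.51 for Thbs1, 3.83 to -0.41 for Fos, 2.18 to -1.25 for Fosb, 4.12 to -0.18 for Fcgr3, 4.06 to -0.26 for Lyz2 and 0.25 to -0.74 for Adam8. These are their lowest values with 1 library left out, and the highest were 4.28 (Cd36), 3.40 (Nlrp3), 4.75 (Il1a), 2.60 (Thbs1), 4.38 (Fos), 2.71 (Fosb), 4.69 (Fcgr3), 4.6 (Lyz2) and 0.58 (Adam8). Of the genes called and named by the rule or from lists, 95 of 126 kept their call in all alternatives for high glucose, 95 of 145 for the mimic, 131 of 137, 128 of 134 and 127 of 136 for the control comparisons, and 46 of 85 for the difference of effects.

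The replicate numbers of the labels gave no sign of pairing, except between inhibitor control and high glucose, where pairing stays open. Deviations of same-numbered libraries correlated at -0.17 to 0.10 across genes. Every library correlated best with its own number in the inhibitor control comparison (6 of 6), as a hint from the data, and 0 to 3 of 6 did in the others. With the replicate number as a block 3500, 4883 and 0 genes were called for high glucose, mimic and inhibitor, 11844, 11950 and 11146 for the control comparisons and 1816 for the difference of effects. Depth of 33655916 to 37928790 reads put levels under 0.0791 to 0.0891 CPM out of reach.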

Other observations

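Tests of the macrophage and Txnip patterns, and the test of UTR properties, were chosen after the results were seen; those of the miR-200 family and of the vehicle and high glucose libraries, and the regroupings, were set before their results were seen. The marker levels that follow leave it in doubt that the cells are the line named in the labels. H19, a long noncoding RNA of fetal muscle, lay at 1525 unscaled CPM in vehicle, 2356 in high glucose, 757 and 638 in the inhibitor group and its control, and 33.8 and 27.4 in the mimic group and its control. The skeletal muscle regulator Myod1 lay at 0.743 to 1.91 unscaled CPM in the group means, near Nkx2-5, a cardiac regulator, at 0.248 to 2.01 unscaled CPM. Phospholamban (Pln) had 1 read in vehicle and 0 in the other 5 groups, and cardiac actin (Actc1) lay at 0 to 0.347 unscaled CPM.

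Of 9 measured macrophage markers 7 (77.8%) lay over 5 times above the highest other library in mimic replicate 2, just under the 80% set for RNA of macrophages, against 0 of the endothelial, fibroblast and smooth muscle markers, and Lyz2, Saa3, Arg1 and Ctss reached 870, 413, 375 and 306 CPM. Macrophage RNA in that library is a candidate explanation that stays open, since Cd68 and Cd14 also lay at 9.67 to 43.8 and 2.94 to 19 CPM in the other libraries. An effect of the mimic is argued against by a list median of -0.18 without the library. A sample from a group outside the mimic pair is argued against too. Mimic replicate 2 correlated at 0.981 with the other mimic libraries and at most 0.951 with libraries outside the pair. Mimic and mimic control libraries correlated at 0.980 to 0.994, so these values do not address a sample of the mimic control. Reads passed from that library may account for the low level of these transcripts in the other 17, since 2.56% of 39 genes over 20 times above every other library in it (at least 500 reads) lay under 0.5 times the median share of 1.91%, in a range of 0.852% to 3.50% that the rule caps at 5%. Macrophage RNA at a low level in every culture would give this too and stays open. Txnip had 87026 reads summed over the 6 untransfected libraries and a median of 26 reads (19 to 71) in the 12 transfected ones. At that median, at most 0.0299% of its reads passed from the untransfected to a transfected library. Passing at a share near 1.91% was therefore not general between the libraries. B4galnt2, Try5, Col4a4, Tenm2 and Acox2 lay further above high glucose with the mimic control than passing at that share would leave. This argues against such passing from the mimic control libraries. The levels of these genes in mimic replicate 2 were not compared, so passing out of that library was not bounded.

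Genes with miR-200a-3p sites were higher in high glucose than in vehicle. UTR length, GC content and expression are argued against as the whole cause, since the seed match stayed at percentile 99.997 of all words with them as covariates. The word of miR-200b, miR-200c and miR-429 reached percentile 98.2 (98.224), between the bounds set, so loss of the whole family in the high glucose libraries stays open. Against vehicle, that word lay at percentile 14.1 in the mimic control and 54.0 in the inhibitor control. These values give no sign of a loss of the whole family in every high glucose group. A loss of activity in the libraries labelled high glucose alone is argued against, as the word lay at percentile 69.4 in the inhibitor control against high glucose and 77.2 in the mimic control. Activity delivered to the libraries labelled vehicle, or a fall of miR-200a-3p or miR-141 activity in every high glucose group, may account for percentile 99.934 in the mimic control against vehicle, a value that shares the vehicle libraries with the pattern, and these cannot be separated here. Site genes stood out less against shuffled words in the controls. For 8mer sites 52 of 419 words were as high in the mimic control against vehicle and 13 in the inhibitor control against vehicle. For any site 9 of 419 words were as high in each.

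Txnip lay near 0 in the negative controls. Glucose shortage in the transfected cultures at harvest may account for it, since Arrdc4, another gene of the same glucose sensor, changed by -4.29 with the mimic control and -4.55 with the inhibitor control, and the unfolded protein response list passed camera upward in both comparisons (0.0796 with an estimated correlation for the mimic control), while the glucose-responsive list passed downward with the mimic control and not with the inhibitor control (median -0.45, camera adjusted p = 0.368). Arrdc4 shares its sensor with Txnip, so it cannot tell glucose shortage from another cause of lower sensor activity. The G2 and M phase list rose in both comparisons and was not weighed in this test. A trend by GC content or length from library making or sequencing is argued against. With both corrected, Txnip still changed by -8.80 with the inhibitor control, the smaller of both changes. A culture batch cannot be told apart from transfection, because no transfected group shares a cluster with an untransfected one and their highest correlation was 0.920. An effect of transfection itself stays open as untested.

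Regrouping 3 libraries against 3 gives 10 splits, too few for a share under 0.05. The real counts were 3652 for high glucose (highest other 22, 1 of 10 splits as large), 5087 for the mimic (0, 1 of 10), 11891, 11977 and 11181 for the control comparisons (0, 1 of 10 each) and 0 for the inhibitor (1, 10 of 10).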
